A study of Mus musculus with 4 samples.

How the data were processed

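RNA was measured in group 2 innate lymphoid cells (ILC2), tissue-resident lymphocytes that secrete type 2 cytokines, taken from the pancreatic islets of C57BL/6j mice that had been fed or fasted. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with CEL-seq2, a 3' end method in which each sample carries a barcode and several samples are sequenced in one file. The submitters' processing notes name the aligner STAR, edgeR and the mouse build mm10, with versions not given in the sources used here. The deposited values are whole-number counts per gene, not normalised; whether they count reads or molecular identifiers is not given in the sources used here. The 4 sequencing files of the series hold libraries of both treatments, so the treatment of a library was read from its column name, with the columns named control taken as fed.

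The table's columns outnumbered the sequencing files in each treatment. At most as many columns as files were used, so 4 fed and 4 fasted libraries entered every step, and 2 further columns, the lowest total of each treatment, were not used here. That rule was set after the totals and the first rows had been seen and before any comparison; the limit itself rests on counting each sequencing file once under each treatment. Libraries are named by group and by the number in their column names (1, 3, 4 and 5). Nothing in the labels says whether the libraries came from separate mice, so p-values measure only the spread between these libraries, which may be partly technical. Within each group no 2 libraries agreed within counting noise (chi-square per gene of 15.0 or more), so none were averaged; 2 libraries made from 1 sample would differ as well, so this does not show that they are independent.

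The table held 15835 genes and 11 rows of ERCC spike-in controls with 20 counts in all, which were left out. Library totals ran from 1797504 to 25252366 counts. Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group kept 7700 genes, library sizes were scaled with TMM factors, and the robust quasi-likelihood test compared fasted with fed without covariates. P-values were two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. Log2 fold changes are fasted minus fed with their standard error (SE), and levels are CPM (counts scaled by library size) over TMM-scaled library sizes, as mean ± SD with n = 4 per group. The common biological coefficient of variation was 0.506.

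Before the data were examined, 30 gene lists were fixed, together with the rule for named genes and the alternatives. The 24 lists with at least 3 tested genes were compared with all other genes by camera in limma 3.58.1 on log2 CPM with a prior count of 2 and an inter-gene correlation preset to 0.01, adjusted over the lists. The named genes are, where no gene passes, the 5 with the smallest p in each direction, a fixed set of 18 ILC2, cytokine, trafficking and fasting genes, the 4 members with the smallest p of each passing list and the 3 most abundant genes of each marker list of other cells. Some of the genes this rule takes are not reported here. Older symbols used by the table were matched for 18 list members by synonym and chromosome. For other cell types, CPM of library totals were summed over 9 marker lists and log2 sums were compared by an exact two-sided permutation test over 70 assignments, whose smallest possible p is 0.0286. Coordinates come from GENCODE vM21, which is on the same build, matched by symbol and chromosome.

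Alternatives were other scaling factors, other filters on low counts, DESeq2 1.42.0, limma-voom with quality weights, a replicate block, each library left out, and removal of acinar and islet marker genes. For lists, an estimated correlation and fry were added. After the data had been seen, a covariate for acinar RNA, leaving out the 2 acinar-poor fasted libraries, and thinning to 1797504 counts were added, along with 3 further gene lists. The column numbers were checked for pairing by the correlation of deviations from the group means over tested genes. Libraries of the same number correlated at 0.23, 0.14, 0.50 and 0.13, all above 0.1, so the numbers were taken to pair the libraries. Among unlike numbers, fed library 4 with fasted 5 (0.215) and fed 1 with fasted 3 (0.197) correlated more than 2 of these pairs, and the others ran from -0.405 to 0.07. This pairing rests on the column names and these values, since the labels do not say what a number marks, and the numbers also go with the acinar share.

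The tests were tested on simulated data with the real means, dispersions and library sizes, in which 200 of 7700 genes were changed. For fasted against fed, edgeR recovered 42% of 4-fold and 3% of 2-fold changes with 2 false calls among 47, DESeq2 recovered 64% and 9% with 26 false calls among 99, and limma-voom recovered 38% and 1% with 3 false calls among 42. Camera with the preset correlation found 20 of 20 lists shifted by 0.7 and called 2 of 40 unshifted lists. An estimated correlation found 18 and called 1, and fry found 20 and called 1. Genes were simulated as independent, so these false call counts do not carry over to lists whose members move together. In the real data the estimated correlation was 0.43 for ribosomal proteins, 0.77 for mitochondrially encoded genes and 0.99 for acinar markers.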

Results

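Gene expression was profiled in ILC2 from pancreatic islets of fed and fasted mice, to ask how fasting alters genes associated with the function of these cells. Each group held 4 libraries. Total counts were 1797504, 5855609, 25252366 and 4191852 in fed libraries 1, 3, 4 and 5, and 2041697, 2546920, 7839555 and 9366807 in fasted libraries 1, 3, 4 and 5. Between 9537 and 14056 genes had at least 1 count in a library.

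Much of the RNA carried transcripts of acinar cells, the exocrine cells that surround the islets and secrete digestive enzymes. The 17 acinar marker genes took 38.8% ± 9.98 of counts in fed and 25.1% ± 26.4 in fasted libraries (SD, n = 4). The wide fasted spread came from fasted libraries 1 and 3, with 2.17% and 2.42%, against 46.5% and 49.3% in fasted libraries 4 and 5. The most abundant listed markers were Cpa1, Ctrb1 and Clps, a carboxypeptidase, a chymotrypsinogen and a colipase. Levels of single genes are CPM over TMM-scaled library sizes, with factors from 0.54 to 2.11. They are not on the scale of these shares or of the marker sums, which are over library totals. On the TMM scale Cpa1 stood at 138055 ± 98495 CPM in fed and 111771 ± 126223 CPM in fasted libraries. The gene with the most counts in each fed library and in fasted libraries 4 and 5 was 2210010C04Rik, which is not on the list. It took from 12.7% (fed library 1) to 20.7% (fed library 4) of their counts and was not the top gene in fasted libraries 1 and 3. The listed markers may thus understate acinar RNA, and removing them left this gene in. The exact permutation test over 9 summed marker lists could hardly pass: 1 list at the smallest possible p adjusts to 0.26, and at least 6 lists at it would be needed, so that none passed says little about differences. Acinar sums had a log2 difference of -1.85 (exact permutation p = 0.40, adjusted p = 0.64). B cell markers had the smallest p, at 2.28 ± 1.33 CPM in fed and 6.20 ± 1.24 CPM in fasted libraries (exact permutation p = 0.0286, the smallest possible; adjusted p = 0.26). The log2 differences and adjusted permutation p were -1.32 and 0.51 for islet endocrine markers, 1.08 and 0.51 for T cell markers, 1.02 and 0.58 for mast cell, basophil and eosinophil markers, and 0.37 and 0.64 for NK, ILC1 and ILC3 markers. They were 0.40, -0.07 and 0.07 for myeloid markers, for ductal, stromal and endothelial markers and for red cell markers, each with an adjusted permutation p of 0.97. The permutation ignored the pairing of column numbers. Within every same-number pair the fasted library was lower for islet endocrine markers. It was higher in each for B cell, T cell and mast cell, basophil and eosinophil markers. These sums are over library totals, so the low acinar shares of fasted libraries 1 and 3 raise the share of all other RNA there. The remaining lists went both ways, and so few pairs cannot pass the threshold. The transthyretin gene Ttr, abundant in islet endocrine cells, stood at 82.0 ± 52.6 and 29.0 ± 35.6 CPM, the B cell receptor component Cd79b at 1.71 ± 0.82 and 4.69 ± 1.61 CPM, the antigen presentation gene Cd74 at 48.0 ± 7.03 and 59.6 ± 60.1 CPM, the epithelial keratin Krt18 at 36.1 ± 22.5 and 26.1 ± 30.6 CPM and the beta globin gene, listed as Beta-s, at 308 ± 267 and 208 ± 75.8 CPM in fed and fasted libraries. Some of these means rest on 1 library: without fed library 4 fed Beta-s was at 176 CPM, below fasted, and without fasted library 1 fasted Cd74 was at 29.8 CPM, below fed. Without fasted library 4 fasted Ttr was at 14.3 CPM, and without fasted library 5 fasted Krt18 was at 14.0 and fasted Cpa1 at 72854 CPM. Islet hormone transcripts were scarce, with 21 counts of Ins2 in fed libraries, 16 of them in library 5, and 80 in fasted libraries, 73 of them in library 3.

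**Figure D1:**
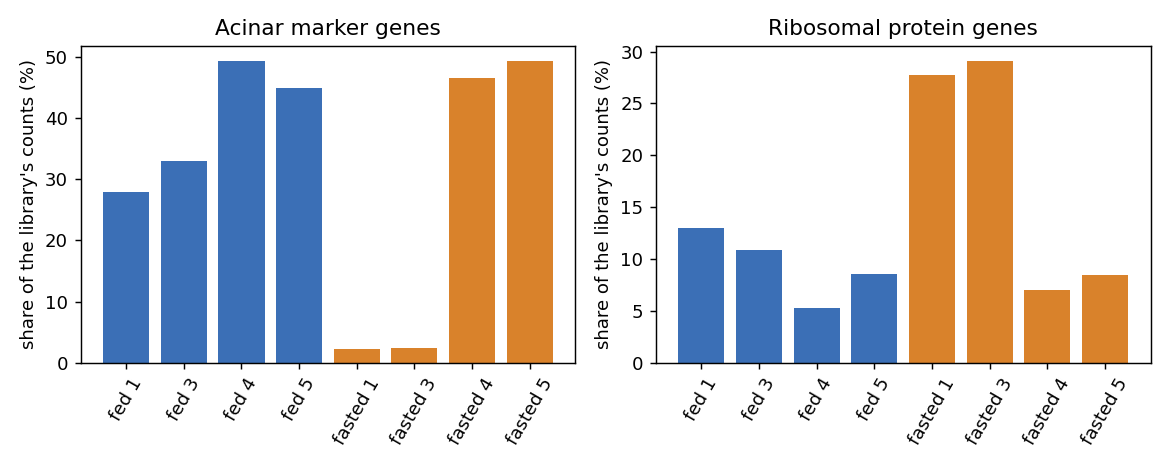
Share of each library's counts (y axes, %) taken by the acinar marker genes (left) and the ribosomal protein genes (right), 1 bar per library, fed in blue and fasted in orange. Acinar genes took 2.17% and 2.42% in fasted libraries 1 and 3 and at least 27.95% in each of the others.

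No single gene passed the threshold between fasted and fed ILC2. Rbm3, a cold-inducible RNA-binding protein, had the smallest p among genes with higher fasted levels. It stood at 92.8 ± 8.98 CPM in fed and 233 ± 29.1 CPM in fasted libraries, a log2 fold change of 1.33 ± 0.20 (SE; edgeR, Benjamini-Hochberg adjusted p = 0.14), and the fed and fasted libraries did not overlap. The next genes with higher fasted levels, none of them called, were Carns1 (carnosine synthase, log2 fold change 1.96 ± 0.39), Wipf3 (1.91 ± 0.39), the transcriptional cofactor Lmo4 (0.92 ± 0.19) and the RNA gene 1500012F01Rik (1.39 ± 0.29). Those with lower fasted levels, also not called, included Nisch (-1.39 ± 0.32), Myadm (-1.25 ± 0.29) and the ribosomal RNA precursor Rn45s (-1.58 ± 0.37). In mm10, Rbm3 lies on chromosome X at 8138975 to 8145880.

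Of the 7700 genes tested with edgeR, 0 had an adjusted p under 0.05, and 338 had an unadjusted p under 0.05 where chance gives 385. The latter count was 535 with the replicate block, 714 with limma-voom, 561 without fasted library 4 and 919 of 15661 genes without a filter on low counts, and from 229 to 450 in the other alternatives. Groups did not overlap for 271 genes, or 3.52% of those tested, where chance gives 2.86%. DESeq2 called 6 genes higher, namely Rbm3, Carns1, Wipf3, 1500012F01Rik, Lmo4 and Tsc22d3, and 2 lower, among them Chac1; on simulated data it made 26 false calls among 99. Limma-voom called 0.

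Genes of sterol and fatty acid synthesis, which make cholesterol and lipids, were lower as a group in the fasted libraries. Of 22 tested members 19 had a negative log2 fold change, with a mean of -0.99 and a median of -0.70. The list passed by camera (Benjamini-Hochberg adjusted p = 3.33e-09; adjusted p = 0.13 with an estimated correlation). Adjusted over the list alone, 7 members fell, 0 rose and 15 did not pass, against 0 over all genes. These included the farnesyl diphosphate synthase Fdps, from 8.02 ± 1.83 to 2.75 ± 0.66 CPM, and the fatty acid desaturase Scd2, from 14.1 ± 11.4 to 3.58 ± 0.54 CPM (fed 8.72 without fed library 4). With the acinar-poor fasted libraries 1 and 3 left out the mean was -1.09. Of the fatty acid members, Fasn, Acaca and Acly had log2 fold changes of -0.38, -0.29 and -0.71, and Scd1 and Srebf1 0.13 and 0.23. None of these passed adjusted over the list alone, but the fatty acid desaturase Scd2 did. Whether the drop differed between the sterol and the fatty acid members was not tested.

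**Figure D2:**
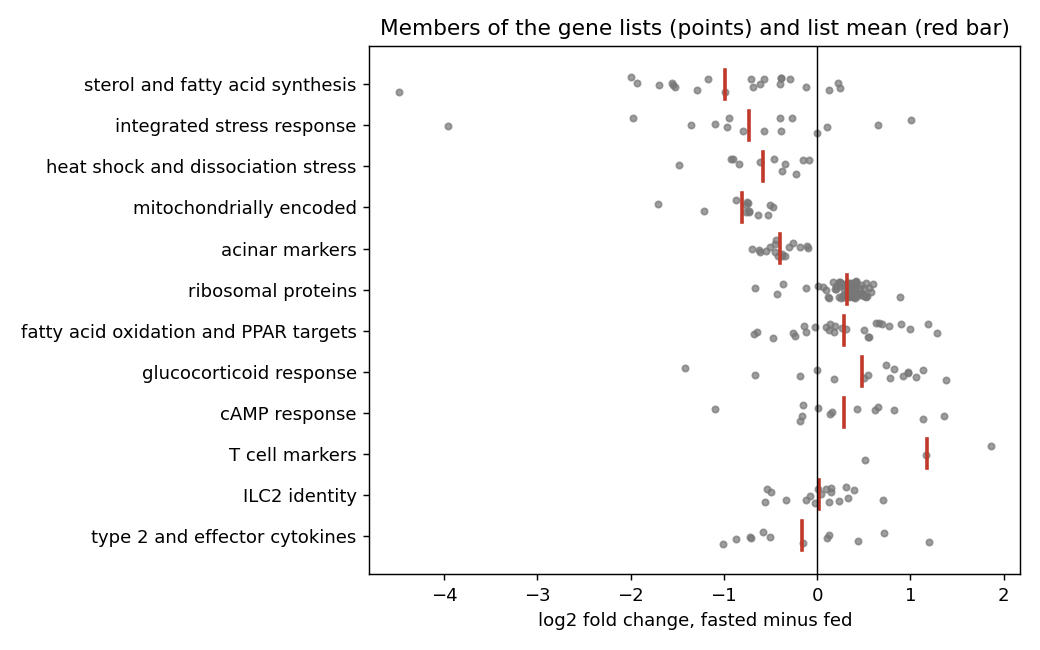
Log2 fold change, fasted minus fed (x axis), of each tested member of 12 gene lists (y axis); points are genes and the red bar is the list mean. The sterol and fatty acid synthesis list lies lowest, with a mean of -0.99, and the ILC2 identity list has a mean of 0.02.

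Genes of fatty acid oxidation and PPAR targets were higher as a group. Of 26 tested members 18 had a positive log2 fold change, with a mean of 0.29 (camera, adjusted p = 0.011; adjusted p = 0.16 with an estimated correlation). Adjusted over the list alone, 3 rose, 0 fell and 23 did not pass. These were Cpt1a, which carries out the rate-limiting step of fatty acid entry into mitochondria, from 11.5 ± 1.22 to 28.0 ± 6.70 CPM, the lipid droplet protein Plin2, from 23.8 ± 3.02 to 47.6 ± 7.90 CPM, and the thiolase Acaa2, from 31.0 ± 7.60 to 57.5 ± 7.86 CPM. The carnitine carrier Slc25a20 had a log2 fold change of 0.77 ± 0.29. Cpt1a lies on chromosome 19 at 3322334 to 3385733. Without fasted library 4 the list had a mean of 0.19 and an adjusted p of 0.11, and with library totals alone an adjusted p of 0.056.

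The glucocorticoid response list was also higher, with 12 of 16 members positive and a mean of 0.48 (camera, adjusted p = 0.033; adjusted p = 0.23 with an estimated correlation). Adjusted over the list alone, 2 rose, 0 fell and 14 did not pass. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, went from 22.8 ± 7.79 to 58.9 ± 13.5 CPM and the clock gene Per1 from 31.4 ± 6.70 to 68.6 ± 21.4 CPM. Irs2 and Cebpd, which did not pass, had log2 fold changes of 0.97 ± 0.32 and -1.42 ± 0.52, and Fkbp5, a classical glucocorticoid target, 0.51 ± 0.44; without the acinar-poor fasted libraries Irs2 was at 0.42 ± 0.33. With the replicate block the list no longer passed, at a mean of 0.23 and an adjusted p of 0.080; it was also lost with library totals alone (adjusted p = 0.19) and without fed library 1 (0.069), 3 (0.091) or 4 (0.067) or fasted library 4 (0.11) or 5 (0.13). Cyclic AMP response genes had a mean of 0.29 over 13 members (camera, adjusted p = 0.018; adjusted p = 0.33 with an estimated correlation). Per1, the repressor Crem and the AP-1 member Fosl2 rose adjusted over the list alone, and 10 members did not pass; Fosl2 went from 0.82 to 0.48 without the acinar-poor fasted libraries. The call was lost with library totals alone (0.19), with the acinar covariate (0.19) and without the 2 acinar-poor fasted libraries (0.18).

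Stress-response genes were lower as a group in the fasted libraries, 2 of which were poor in acinar RNA. Of 15 integrated stress response members 12 were negative, with a mean of -0.73 (camera, adjusted p = 0.0033; adjusted p = 0.33 with an estimated correlation). Adjusted over the list alone, 2 fell, 0 rose and 13 did not pass. These were the glutathione-degrading enzyme Chac1, from 68.4 ± 29.1 to 4.35 ± 5.76 CPM (fasted 1.56 without fasted library 4), and the serine synthesis enzyme Psat1, from 124 ± 27.1 to 57.8 ± 18.6 CPM. Phgdh, the first enzyme of that pathway, had a log2 fold change of -0.95 ± 0.48 and the phosphatase subunit Ppp1r15a one of 0.66 ± 0.25; without the acinar-poor fasted libraries they were at -0.39 ± 0.47 and 0.27 ± 0.31. All 11 heat shock and dissociation stress members were negative, with a mean of -0.58 (camera, adjusted p = 0.017; adjusted p = 0.49 with an estimated correlation) and 0 of 11 passing adjusted over the list alone. Hsph1, Hsp90ab1, Hspd1 and Hspa1b had log2 fold changes of -1.48 ± 0.69, -0.62 ± 0.33, -0.83 ± 0.53 and -0.90 ± 0.61, and -0.62, -0.23, -0.34 and -0.25 without fed library 3; without fasted library 4 Hsph1, Hspd1 and Hspa1b were at -2.27, -1.28 and -1.36. Without the 2 acinar-poor fasted libraries the adjusted p was 0.80 for the integrated stress response and 0.94 for heat shock. Leaving out fed library 5 gave 0.057 for the former, and leaving out fed library 3 or fasted library 1 gave 0.43 or 0.25 for the latter.

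Ribosomal protein genes had higher levels, uncertain where the counting could split reads with pseudogene copies, which was not measured, with 71 of 75 positive and a mean of 0.32 (camera, adjusted p = 3.59e-10; adjusted p = 0.34 with an estimated correlation). None of the 75 passed adjusted over the list alone; Rpl37a, Rps20, Rps27a and Rpl17 had log2 fold changes of 0.89 ± 0.29, 0.58 ± 0.22, 0.51 ± 0.20 and 0.50 ± 0.20. Ribosomal protein genes took 27.7% and 29.1% of counts in acinar-poor fasted libraries 1 and 3 and between 5.24% and 13.0% in the others. Without those 2 fasted libraries the list mean was 0.25 (camera with the preset correlation, unadjusted p = 1.35e-04). With the acinar covariate it was 0.27 (unadjusted p = 8.57e-07 by the same test). The 13 mitochondrially encoded genes were all negative, with a mean of -0.80 (camera, adjusted p = 0.0023; adjusted p = 0.49 with an estimated correlation) and 0 passing adjusted over the list alone. The respiratory complex I subunits mtNd6, mtNd5, mtNd1 and mtNd3 had log2 fold changes of -1.70 ± 0.61, -1.21 ± 0.63, -0.76 ± 0.42 and -0.73 ± 0.42; without fed library 1 mtNd5 was at -0.47, and without fed library 4 mtNd1 and mtNd3 were at -0.35 and -0.33. That call was lost without fed library 1 (0.099) or 4 (0.067), with the acinar covariate (0.13) and without the acinar-poor fasted libraries (0.20). Acinar markers passed as lower, with a mean of -0.40 (camera, adjusted p = 3.99e-06; adjusted p = 0.43 with an estimated correlation, itself 0.99), and 0 of 17 passed adjusted over the list alone. Cela2a, Cel and Reg1, pancreatic enzymes and a secreted lectin, had log2 fold changes of -0.69 ± 1.41, -0.62 ± 1.38 and -0.54 ± 1.32, and with a library left out ran from -1.58 to -0.30, -1.58 to -0.23 and -1.24 to 0.23. The acinar mean was -2.28 with the replicate block and -2.75 with limma-voom, and turned to 0.34 with the acinar covariate, to 0.59 without the acinar-poor fasted libraries and to 0.07 without fed library 4, and with the DESeq2 statistics the list did not pass (adjusted p = 0.28). T cell markers passed on 3 tested genes with a mean of 1.18 (camera, adjusted p = 0.0027; adjusted p = 0.16 with an estimated correlation): Lef1, which rose adjusted over the list alone (1.16 ± 0.37), Cd3g (0.51 ± 0.22) and Cd3e (1.86 ± 0.99). Without a filter on low counts, where 7 genes were tested, that mean was -0.65.

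**Figure D3:**
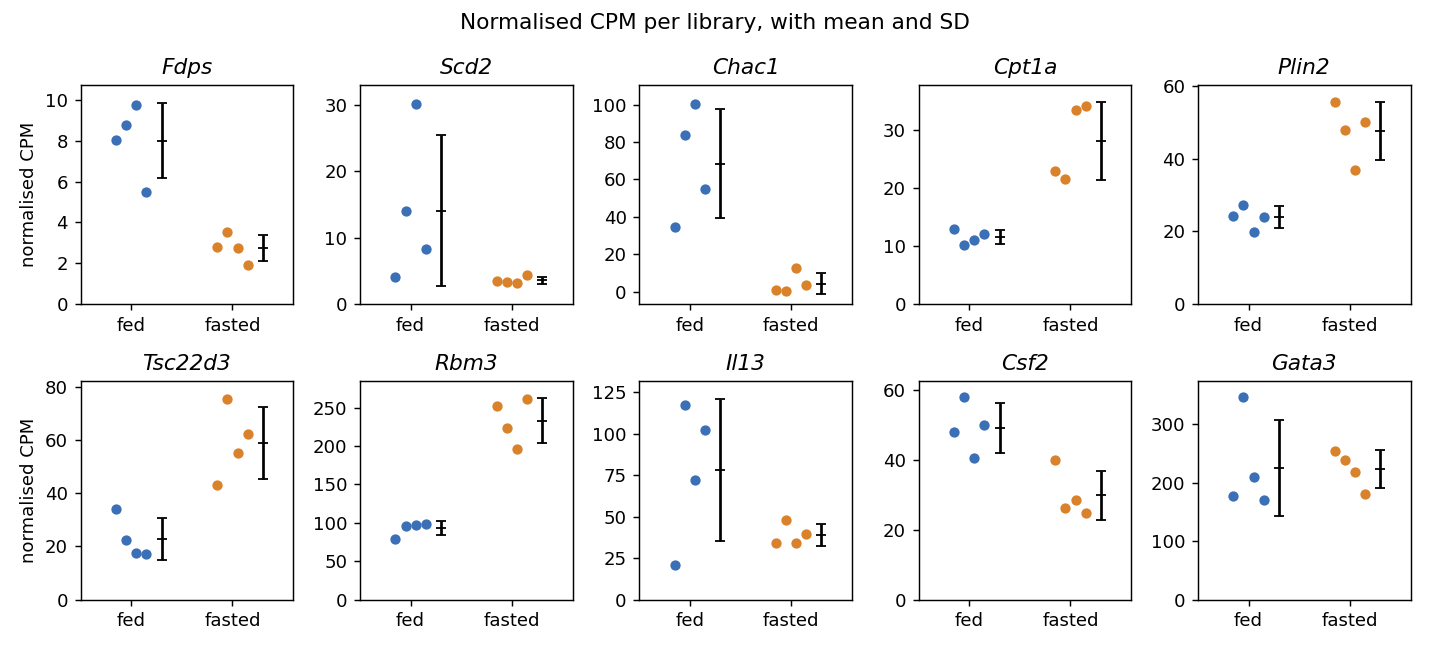
Normalised CPM (y axes) of 10 genes in each of the 4 fed (blue) and 4 fasted (orange) libraries; each point is a library, the black bar the mean and the whiskers the SD. Rbm3 is at 97.96 CPM or below in the fed libraries and higher in each fasted one, and Gata3 overlaps between the groups.

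The identity genes of ILC2 did not pass in either direction. The list had a mean of 0.02 over 18 tested members (camera, adjusted p = 0.63), with 0 members passing adjusted over the list alone. Gata3, the lineage-defining transcription factor, stood at 225 ± 82.2 CPM in fed and 223 ± 32.2 CPM in fasted libraries, a log2 fold change of -0.02 ± 0.26. The IL-33 receptor Il1rl1 had 0.15 ± 0.31, the IL-7 receptor Il7r 0.39 ± 0.24 and the inhibitory receptor Klrg1 0.01 ± 0.27. Effector cytokines did not pass as a list by camera either, with a mean of -0.16 over 12 tested members (camera, adjusted p = 0.34) and 0 members passing adjusted over the list alone. Members went both ways, 5 positive and 7 negative. Calca had the smallest p, at 1.20 (edgeR, unadjusted p = 0.0093, Benjamini-Hochberg adjusted p = 0.84). A mixed fry test, for changes in either direction and not against other genes, gave an adjusted p of 0.0097. Il13, a main type 2 effector cytokine, stood at 78.2 ± 42.6 CPM in fed and 38.9 ± 6.53 CPM in fasted libraries, a log2 fold change of -1.01 ± 0.42 (edgeR, Benjamini-Hochberg adjusted p = 1.00). Csf2, which encodes GM-CSF, stood at 49.2 ± 7.12 and 29.9 ± 6.92 CPM without overlap, at -0.72 ± 0.25 (edgeR, Benjamini-Hochberg adjusted p = 0.98). Il5 had -0.51 ± 0.58 and the growth factor Areg -0.15 ± 0.38; with a library left out Il5 ran from -1.13 (without fasted library 1) to -0.12 (without fed library 5) and Areg from -0.41 (without fasted library 1) to 0.17 (without fed library 3). Both moved once acinar RNA was allowed for: Il5 was at -1.32 ± 0.64 with the acinar covariate and -1.48 ± 0.67 without the 2 acinar-poor fasted libraries, and Areg at -0.51 ± 0.41 and -0.57 ± 0.46, none called. The same 12 cytokine genes had means of -0.34 and -0.38 in these 2 settings, and the list did not pass (camera, adjusted p = 0.16, and 0.12 with Il4 also tested, which put the mean at -0.31). Counts of Il4, summed over libraries of unequal depth, were 34 in fed and 28 in fasted libraries (18 of these in fasted library 4). Those of the neuromedin receptor Nmur1 were 29 and 10, of S1pr1 62 and 9, and of the proliferation marker Mki67 1 and 2, too few to be tested; fed library 4, the deepest, held 21 of the 29 and 53 of the 62. The homing receptors Ccr9 and Cxcr4 had log2 fold changes of 1.37 ± 0.45 and 0.54 ± 0.25, not called.

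The other lists did not pass by camera. Mean log2 fold changes and adjusted p were 0.25 and 0.068 for immediate early genes, 0.25 and 0.068 for FOXO targets, autophagy and lysosome, -0.40 and 0.068 for interferon response, and 0.25 and 0.12 for the circadian clock. They were 0.21 and 0.13 for migration and tissue residency, -0.10 and 0.11 for nuclear oxidative phosphorylation, -0.43 and 0.13 for ductal, stromal and endothelial markers, -0.20 and 0.26 for proliferation, and 0.35 and 0.33 for checkpoint and cytokine feedback. They were 0.12 and 0.37 for neural, hormone and lipid receptors, 0.08 and 0.54 for glycolysis and glucose uptake, and 1.14 and 0.93 for myeloid markers. Summed myeloid markers stood at 1306 CPM in fasted library 1 and at most at 146 CPM in any other library. Without fasted library 1 the myeloid mean was -0.88 (camera, adjusted p = 0.025). The ductal, stromal and endothelial mean turned to 0.34 with library totals alone (adjusted p = 0.0043). With the acinar covariate the interferon and FOXO lists passed, at means of -0.62 and 0.36 (adjusted p = 0.0093 and 0.0086). With the DESeq2 statistics the immediate early, FOXO, interferon and nuclear oxidative phosphorylation lists passed (adjusted p = 0.016, 0.016, 0.035 and 0.047). Adjusted over the list alone, Per1 and Tef of the clock list rose. Islet endocrine, B cell, NK, ILC1 and ILC3, mast cell, basophil and eosinophil, red cell and sex-linked lists had fewer than 3 tested genes and were not tested as lists.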

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

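In each group of 4 libraries, 1 library was noted when its gap to the nearest other was most of the group's range; chance gives about 1 in 20 groups, and 23 of 190 were noted here. Many concern genes with almost no counts, where 1 library holds the few counts there are.

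Fasted library 1 held myeloid transcripts far above its group, with myeloid markers summing to 1306 CPM against at most 85.2 in the other fasted libraries. Its antigen presentation genes Cd74, H2-Eb1 and H2-Ab1 stood at 149, 152 and 121 CPM, against at most 39.05, 24.3 and 15.9, and Siglec5 at 2.81 CPM. Single genes are over TMM-scaled sizes (factor 2.11 in this library) and the sum is over library totals, so they cannot be read as parts of it. Fasted library 3 held the islet hormone genes Ins2 and Ins1 at 14.25 and 9.95 CPM and the collagen gene Col3a1 at 26.7 CPM. Fasted library 4 held the chaperone Hsph1 at 15.3 CPM against at most 4.10, and fasted library 5 held Cd79a at 4.93, Ncr1 at 0.19 and Fcer1a at 0.76 CPM.

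Among fed libraries, Rbm3 was lowest in library 1 at 79.4 CPM against at least 96.5, Lmo4 highest in library 3 at 400.3 CPM against at most 354, and Rps20 highest in library 5 at 3404 CPM against at most 2611. Fed library 3 also held Ins1 at 0.68, Ncr1 at 0.54 and Ifng at 0.41 CPM. Fed library 4 held Cd79a at 1.85, Siglec5 at 0.07, Alas2 at 5.32 and Hba-a1 at 0.07 CPM, and fed library 5 held Mki67 at 0.34 CPM.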

How the results depend on the processing

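The acinar covariate, leaving out the 2 acinar-poor fasted libraries, and thinning were chosen after the data were seen. The count of called genes, 0, moved to 1 with library totals alone, to 1 without a filter on low counts and to 8 with DESeq2, and was 0 in every other setting, including each library left out and an adjusted p under 0.1. The number of passing lists, 10, became 0 with an estimated correlation and 4 with the directional fry test. Fry tests for a change and not against other genes. The 4 were the sterol, fatty acid oxidation and T cell lists, and the immediate early list, which is not among the 10. The cause was not tested beyond the gene-to-gene correlation that these 2 tests allow for. Passing lists ranged from 8 to 15 with a library left out and numbered 9 with the replicate block, which also left 0 genes called; it changed no other list call than that of the glucocorticoid list. Library totals alone shifted the median of all genes by 0.51 and turned the ductal, stromal and endothelial list to 0.34. The T cell list turned to -0.65 without a filter, where 7 genes were tested. Acinar markers turned to 0.34 with the covariate and 0.59 without the 2 acinar-poor libraries, and ran from -1.22 to 0.073 with a library left out; myeloid markers ran from -0.88 to 1.72. The count of other cell types, 0, could hardly move, given the smallest p of its test. Of values that passed neither as reported nor in the alternative, 12 of other cell types, 64 of named genes and 28 of lists changed sign. At these library sizes, spread and 4 libraries per group, edgeR recovered 42% of simulated 4-fold and 3% of 2-fold changes; how much of that is due to depth was not tested.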

Other observations

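All tests of acinar RNA and of thinned counts, and the added gene lists, were chosen after the data were seen. For the sterol, oxidation, glucocorticoid, stress response, Chac1, Rbm3 and Cirbp tests of acinar RNA, what would count for or against it was also set after values per library or with the acinar covariate had been seen, and the allowance for the spread between genes was added after a first run, as were the test of what remained of the endoplasmic reticulum list and the removal from the T lineage list of genes that fixed lists hold. Chaperones and folding enzymes of the endoplasmic reticulum, a list also chosen then, were lower in fasted libraries in 17 of 17 tested genes, with a mean log2 fold change of -0.91 ± 0.08 (SE over genes). Calr, a calcium-binding chaperone, stood at 174 ± 28.0 CPM in fed and 92.9 ± 16.6 CPM in fasted libraries (log2 fold change -0.90 ± 0.22; edgeR, Benjamini-Hochberg adjusted p = 0.50). The cold-inducible RNA-binding protein Cirbp, chosen after its value was seen beside Rbm3, stood at 32.0 ± 15.2 and 91.8 ± 28.3 CPM (log2 fold change 1.53 ± 0.38; edgeR, Benjamini-Hochberg adjusted p = 0.55). Outside the fixed lists, 6 T lineage genes had a mean log2 fold change of 0.10 ± 0.09 (limma camera across genes, unadjusted p = 0.45).

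Sterol and fatty acid synthesis genes were lower, and fatty acid oxidation and glucocorticoid response genes higher, in the fasted libraries by camera with the preset correlation. With an estimated correlation none of the 3 lists passed (camera, adjusted p = 0.13, 0.16 and 0.23). The glucocorticoid list was also lost with the replicate block (camera, adjusted p = 0.080). Without the 2 acinar-poor fasted libraries the 3 means were -1.09, 0.36 and 0.59, the smallest ratio to the means in all libraries being 1.11. That setting kept fasted libraries 4 and 5 against all 4 fed ones, which broke the pairs of numbers. Any difference that goes with the numbers thus entered the comparison. The acinar marker mean turned to 0.59 there, so the acinar difference was reversed and not removed. Within these limits the kept means argue against the unequal acinar share as the whole cause. The libraries kept held at least 27.95% acinar marker counts, so a response within acinar cells cannot be told apart from one within ILC2. After thinning to equal totals the largest camera adjusted p of the 3 lists was 0.026, which argues against unequal totals. Thinning left the acinar shares unequal, so the depth of the remaining RNA was not equalised. Of the 35 splits of the 8 libraries, 1 gave as small a camera p for the sterol list, the real one (2.77e-10, smallest other 4.75e-08). This is the smallest share that 35 splits can give. It ignores the pairs and was not adjusted over the lists. The 8 splits that part all 4 pairs of numbers are too few for a share under 0.05 (smallest other 5.15e-05). The real split thus stood out for the sterol list, but chance was not excluded. For the oxidation list (2 of 35, 0.0031 against 0.0024) and the glucocorticoid list (2 of 35, 0.014 against 0.00081) another split gave a smaller p, so chance cannot be excluded there either. That the lipid genes follow the feeding state of the mice is a hypothesis, untested beyond these libraries.

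Chaperone and stress genes were lower in fasted libraries, where 2 of 4 held little acinar RNA, and acinar cells are rich in folding enzymes; with an estimated correlation camera no longer passed the integrated stress response and heat shock lists (adjusted p = 0.33 and 0.49). The mean of the endoplasmic reticulum list stayed at -0.37 ± 0.09 (SE over genes) without those 2 libraries and at -0.44 ± 0.09 with the acinar covariate. Acinar markers turned to 0.59 and 0.34 in these settings, the former of which also broke the pairs of numbers. By a rule added afterwards this argues against the unequal acinar share as the source of the whole drop. The SE over genes does not measure the spread between libraries, and a response within acinar cells cannot be told apart from one within ILC2. The endoplasmic reticulum list kept 0.40 of its mean without the 2 libraries, below the limit of 0.5 set before that test was run. By the ratio alone this goes with acinar RNA. The mean fell short of the limit by 0.09 ± 0.06 (SE over genes), so the ratio does not decide it. For the part that went, acinar RNA and fasting cannot be told apart, since the 2 libraries are both fasted and acinar-poor. The integrated stress response list kept 0.46 of its mean and heat shock 0.37, too close to the limit of 0.5 given the spread between genes, so acinar RNA and fasting cannot be told apart for them. Chac1 kept a log2 fold change of -3.32 ± 0.54 with the acinar covariate, which argues against the unequal acinar share as its whole cause. Whether the drop lies in acinar cells or ILC2 cannot be told apart.

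Rbm3 and Cirbp, RNA-binding proteins induced by mild cold, were higher in fasted libraries. Their mean kept 0.87 of its value without the acinar-poor libraries and 1.01 after thinning. Leaving out those libraries broke the pairs of numbers and reversed the acinar difference. Within that limit the kept values argue against unequal acinar shares and unequal totals as the whole cause. Neither setting tells acinar cells from ILC2 as the source, and thinning left the depth of the non-acinar RNA unequal. A lower body temperature of fasted mice may be behind the higher levels of Rbm3 and Cirbp, as may a difference in handling time or temperature. Neither was tested.

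With 0 genes called, all 35 of the splits give at least as many by necessity, which tests nothing; the highest other count was 10. That count came from the split of numbers 1 and 3 against 4 and 5, which points to a structure of the libraries. That split follows the column numbers and also the acinar share, 2.17 to 33.0% against 44.9 to 49.3%, and the 2 were not separated; with the replicate block 0 genes were called. For the 10 passing lists chance could not be excluded, since 2 of the 35 splits gave as many and the highest other was 10. Among the 8 splits that part all 4 pairs of numbers, the others gave between 0 and 5 lists, and their smallest p were 0.043 and 0.031 for the oxidation and glucocorticoid lists; 8 are too few for a share under 0.05.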
